A study of Mus musculus with 6 samples.

How the data were processed

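Gene expression was measured on 6 single-colour Agilent mouse whole-genome arrays, 1 per group. The groups were Foxp3+ and Foxp3- CD4 T cells, sorted by flow cytometry from pooled spleens of non-infected mice and of mice at day 3 and day 5 of Plasmodium yoelii infection. Per the labels, total RNA was labelled with Cy3 by Agilent's Quick Amp procedure. Each array was assigned to its group from its title, and each of the 6 groups holds 1 array, so no group has replicates.

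The authors deposited 1 scanner file per array and 1 table of processed values. Per the file headers, the scanner files were made with Feature Extraction 10.5.1.1, and hold spot intensity values on a linear scale. The processed signal in them was background-subtracted by a spatial fit and detrended, with surrogate values for spots not above background, per the file headers, and it was not normalized between arrays. The raw mean signal and the median local background of each spot are also intensity values in the deposited scanner files. The deposited value table is on a log2 scale, and the way the authors made it is not given in the sources used here. In that table each probe has a median of 0 over the 6 arrays. The column medians are 0.11 for Foxp3+ non-infected, 0.05 for Foxp3+ day 3, -0.06 for Foxp3+ day 5, 0.03 for Foxp3- non-infected, -0.10 for Foxp3- day 3 and 0.05 for Foxp3- day 5. Across probes its columns correlated with the probe-centred scanner values at r = 0.985 to 0.994 with a ratio of SDs of 0.960 to 1.05, so both are on the log2 scale with the same direction. Its scaling between arrays stays unknown: its columns lie -0.20 to 0.46 above the scanner values on the log2 scale.

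The main values were log2 of the processed signal minus each array's 75th percentile over its 43379 non-control spots. Spots with an outlier flag (61 to 231 per array) were left out, and no spot was saturated. Repeated spots were averaged per probe, which gave 41174 probes, and 103 probes with no usable spot on some array were left out. Probes were named through the RefSeq accessions in the reference table of mouse genes (26795 probes), by current symbol (5122), by an older synonym (929) or by the file's own name (8328). For each of the 27988 genes or gene names, of which 19858 are current symbols, the probe with the highest mean over the arrays was used. Probe coordinates are those of the array files, on mouse build mm9 (NCBI37), and no reference genome was used here. Each gene's call as well above background came from the scanner software. The SD between repeated spots of the same probe had a median of 0.067 to 0.095 on the log2 scale, which covers spot noise only. No depth of counting applies to arrays, and the number of arrays limits the precision.

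Foxp3+ and Foxp3- cells were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with infection state as a block, so that the 3 states form 3 pairs. The fit had 2 residual degrees of freedom and a prior of 3.24. Genes well above background on at least 3 of the 6 arrays were tested, 13803 in all, with a two-sided test and Benjamini-Hochberg adjustment at a threshold of 0.05. A pair is 1 Foxp3+ and 1 Foxp3- array of the same infection state, and the spread between pairs may hold real effects of infection. Whether the arrays of a pair came from the same mice is not given in the labels. Gene lists were tested with camera at a preset inter-gene correlation of 0.01, and again with an estimated correlation (statmod 1.5.0). With an estimated correlation camera tests on the 2 residual degrees of freedom of the fit, which leaves little power. No adjusted p with the estimated correlation was under 0.05 for any of the 30 lists tested, which does not measure the effect of correlation alone.

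Each infected array was compared with the non-infected array of the same cell type. With 1 array per group no p-value was computed, and none of these differences has a replicate check. Genes well above background on both arrays were compared, and differences of at least 1 on the log2 scale (2-fold) were counted. A gene list was described by its median and by that median's percentile among 10000 random lists of as many genes matched on mean signal, given as a description of these arrays. Lists with fewer than 3 measured members got no median. A median with floored members also counts members above background on only 1 of the 2 arrays, with dim signals raised to the lowest signal among probes well above background, and it is given at least where its sign turns or it differs by a factor of more than 1.5. Where a gene was well above background on the arrays of only 1 side, the difference is given as "at least N-fold". That bound sets the bright side's mean against the mean, per array of the dim side, of the higher of the probe's own value and the lowest signal among probes well above background.

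Before the data were examined, 31 gene lists were fixed: Treg signature genes, conventional CD4 T cell genes, Treg suppressive mediators, activation and checkpoint genes, type I interferon-stimulated genes, interferon-gamma-induced GTPases and antigen processing genes, cell cycle genes, Th1 genes, follicular helper genes, Th2 and Th17 genes, naive and homing genes, effector homing receptors, cytotoxic genes, IL-2/STAT5 targets, apoptosis, glycolysis, cholesterol synthesis, unfolded protein response, immediate early and heat shock genes, reference genes and T cell identity genes, and markers of B cells, plasma cells, macrophages and monocytes, dendritic cells, neutrophils, erythroid cells, platelets, natural killer cells, CD8 T cells and stromal cells. Lists share members: 19 of the 38 Treg signature genes on the array are also in another list. The rule for named genes was fixed at the same time. It takes the 10 highest and 10 lowest log2 differences of each comparison (for the cell type comparison among genes past the threshold with the same sign in all 3 pairs), and up to 4 measured members of each list with the largest difference. Foxp3, Il2ra, Cd4 and Il10 are always named. Only current gene symbols count. Some genes that this rule names are not reported here.

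The alternatives planned before the data were examined were normexp background correction (offset 50), quantile normalization, the deposited table, the mean over a gene's probes, other filters on dim probes, no block, slide as an added block, a variance trend, an estimated list correlation and leaving out each pair. After the data were seen, 3 alternatives were added: scaling on the 15981 probes above background on all 6 arrays, leaving out 2978 genes whose probes lie in or near patches of spots that stand apart on 1 array, and a normexp model fitted on spots at or above their local background. A spot stands apart if it lies at least 2 on the log2 scale below or above each other array, and it is in a patch if at least 2 other such spots lie within 5 rows and columns. The genes left out are those with a probe within 5 rows and columns of a patch spot on any of the 6 arrays. Most of their own spots do not stand apart, and they are called genes in patches below.

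The steps were tested on simulated data. With 13803 genes, the cell type test recovered 0% of 50 genes changed by 1 on the log2 scale, 62% of those changed by 2, 96% of those changed by 4 and 98% of those changed by 6. It called 8 unchanged genes and 0 of 30 unchanged lists. In each infection comparison 200 of 200 changed genes were counted, and 6 to 13 unchanged genes passed 2-fold. Here the infected array was simulated as the reference plus random noise of a chosen size, with changes well past 2-fold. No slide, patch or array effects were simulated, so these counts check the steps only and give no error rate for the real arrays. Of 40 unchanged lists, 4 lay outside the central 95% of random lists for Foxp3+ day 3, 1 for Foxp3+ day 5, 4 for Foxp3- day 3 and 2 for Foxp3- day 5. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for the list percentiles and plots. No sample was left out.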

Results

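Transcripts were profiled in CD4 T cells from spleens of BALB/c mice carrying a green fluorescent reporter of Foxp3, the transcription factor that defines regulatory T cells. Cells were sorted into regulatory T cells (CD4+CD25+Foxp3+, here Foxp3+) and other CD4 T cells (CD4+CD25-Foxp3-, here Foxp3-). They came from spleen pools of non-infected mice, the reference, and of mice at day 3 and day 5 of infection with Plasmodium yoelii, a rodent malaria parasite. Each of the 6 groups was measured on 1 array. Probes well above background made up 43.2% of spots for Foxp3+ non-infected, 44.2% for Foxp3+ day 3, 52.1% for Foxp3+ day 5, 58.0% for Foxp3- non-infected, 49.1% for Foxp3- day 3 and 45.3% for Foxp3- day 5. Levels are log2 signals relative to each array's 75th percentile.

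The arrays lay on 2 slides, each scanned separately. Slide 1 held Foxp3+ non-infected and Foxp3+ day 3, and slide 2 held Foxp3+ day 5 and the 3 Foxp3- arrays. The Foxp3+ arrays also carried patches of neighbouring spots that were dark on that array alone: 57 spots on Foxp3+ non-infected, 58 on Foxp3+ day 3 and 9 on Foxp3+ day 5, against 0 on each Foxp3- array. Patches of spots bright on 1 array alone held 28 spots on Foxp3+ day 3, 11 on Foxp3+ day 5, 15 on Foxp3- non-infected and 1 on Foxp3- day 5.

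**Figure D1:**
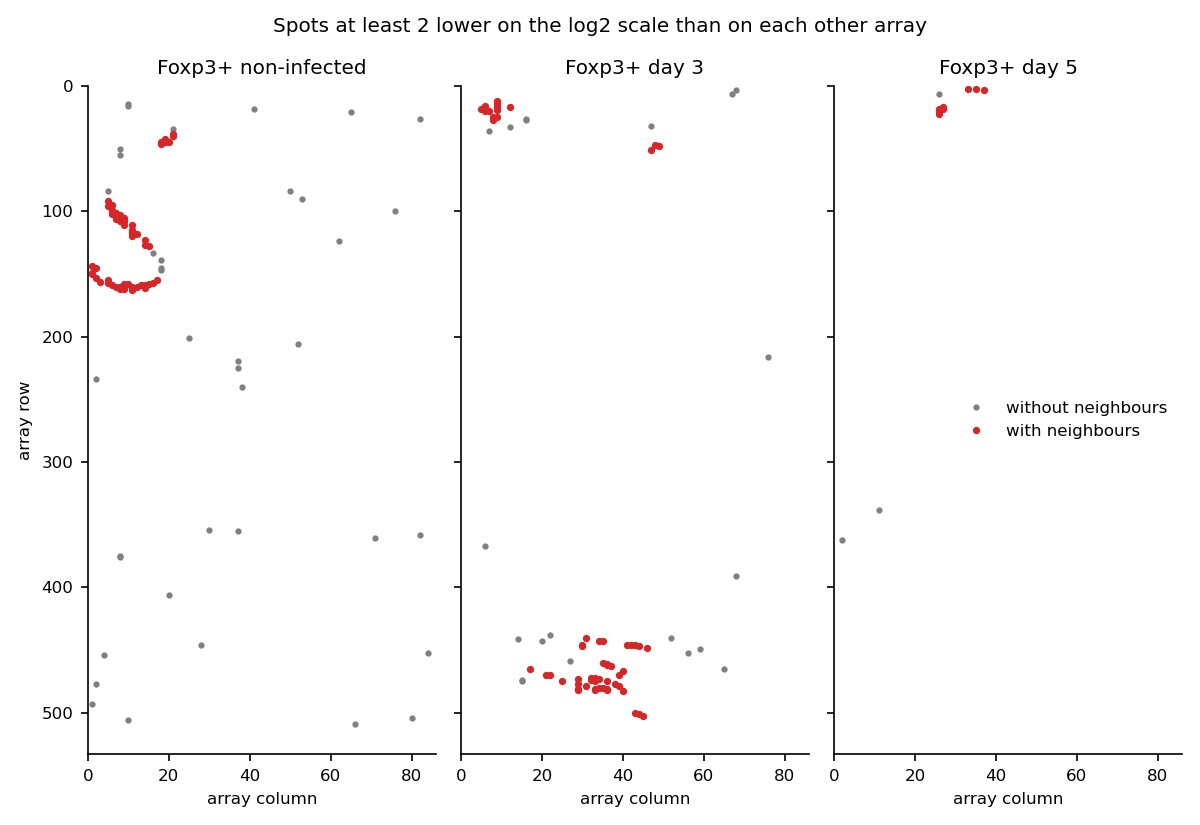
Position on the array (row against column) of spots at least 2 lower on the log2 scale than on each of the other 5 arrays, for the 3 Foxp3+ arrays. Spots with neighbours of the same kind are red: 57 of 95 for non-infected, 58 of 78 for day 3 and 9 of 12 for day 5.

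The genes used for the sort were examined before the others. Il2ra, which encodes CD25, the high-affinity IL-2 receptor chain, had levels of 2.06, 2.55 and 2.42 in Foxp3+ cells (non-infected, day 3, day 5). It was -3.93 in Foxp3- non-infected cells and not well above background in Foxp3- cells at day 3 and day 5. Cd4 ranged from 0.25 to 0.41 in Foxp3+ and from 1.21 to 1.25 in Foxp3- cells. The single Foxp3 probe (chromosome X, 7172158 to 7172217, mm9) was not well above background on any array, so Foxp3 transcripts give no check of the sort.

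Foxp3+ cells were set against Foxp3- cells over the 3 infection states to ask how the sorted fractions differ. The fractions differ in CD25 as well as in Foxp3, so differences tied to either cannot be told apart here. CD4 T cells with CD25 but without Foxp3 were in neither fraction. The genes highest in Foxp3+ cells were Il2ra, with a log2 difference of 6.93 (SE 0.50, n = 3 pairs, limma adjusted p = 0.0121), and Slc7a10, an amino acid transporter, at least 33.5-fold higher. The direction of the Il2ra difference was set in advance by the sort. Areg, which encodes the tissue-repair growth factor amphiregulin, was at least 31.8-fold higher. Klrg1, an inhibitory receptor of differentiated T cells, differed by 6.60, Penk, the enkephalin precursor, by 6.43, Itgae, the integrin CD103, by 6.36, and Tnfrsf9, the co-stimulatory receptor 4-1BB, by 5.5. Cyp4f18, a fatty acid hydroxylase, differed by 5.86, while Dnah7a and Nxpe4 were at least 13.6-fold and 13.9-fold higher. Il2ra and Klrg1 were well above background on 1 of 3 Foxp3- arrays, so the size of their differences rests partly on values below background.

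The genes lowest in Foxp3+ cells were Pdlim4, an actin-associated protein, at -7.70 (SE 0.57, adjusted p = 0.0123), Ggt5, a leukotriene-processing enzyme, at least 26.9-fold lower, and Lrrc75b, at least 19.4-fold lower. Dapl1 was at -5.49, Nsg2 at -4.98, Adh1, an alcohol dehydrogenase, at -4.88 and Il1rl2, an IL-36 receptor chain, at -4.88. Pde5a, a cyclic GMP phosphodiesterase, was at least 7.98-fold lower, Rapgef4, a cyclic AMP-activated exchange factor, at least 7.33-fold lower, and Mctp2, whose probe lies near a spot patch, at least 12.8-fold lower. In Foxp3+ cells Pdlim4 was well above background on 2 of 3 arrays, and Adh1 and Il1rl2 on 1 of 3, so the size of their differences is uncertain.

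**Figure D2:**
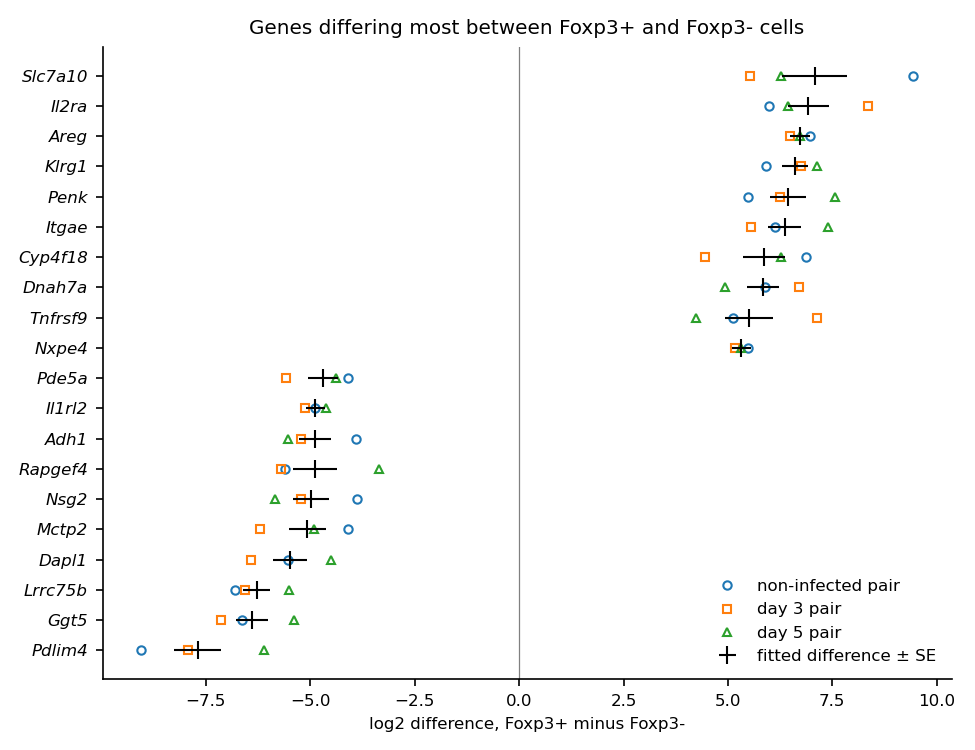
Log2 difference between Foxp3+ and Foxp3- cells (x axis) for the 10 highest and 10 lowest genes past the threshold (y axis). Open symbols are the non-infected, day 3 and day 5 pairs, and black ticks with bars are the fitted difference and its SE, from 7.08 for Slc7a10 to -7.70 for Pdlim4; differences of genes below background in 1 cell type are measured values, not bounds.

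Of 37 Treg signature genes tested, 19 were higher (Il2ra, used for the sort, among them), 0 lower and 18 did not pass, and 32 were higher when adjusted over the list alone. Their median log2 difference was 3.08 (camera adjusted p = 1.85e-37, and adjusted p = 0.258 with an estimated correlation). Besides those above, Ccr8, a chemokine receptor, was at least 12.9-fold higher, and Ebi3, a subunit of IL-35, was 3.21 higher. Ctla4, the inhibitory receptor, differed by 4.33 without passing (adjusted p = 0.0830). Among 16 suppressive mediators, 4 were higher and 12 did not pass, 9 being higher when adjusted over the list alone, with a median of 1.52 (camera adjusted p = 1.16e-10, and adjusted p = 0.258 with an estimated correlation). Il10 (chromosome 1, 132920943 to 132921002, mm9), an immunosuppressive cytokine, differed by 3.33 and did not pass (adjusted p = 0.0964). Ctla4 and Il10 were well above background on 2 of 3 Foxp3- arrays. Both lists share members.

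Of 14 genes typical of conventional CD4 T cells, 6 were lower, 0 higher and 8 did not pass, and 11 were lower when adjusted over the list alone. Their median was -2.15 (camera adjusted p = 4.08e-11, and adjusted p = 0.295 with an estimated correlation). Igfbp4 was at -4.29, Pde3b, a phosphodiesterase known to be repressed by Foxp3, was at least 8.86-fold lower, Themis, a T cell receptor signalling regulator, was at -3.18 and Tcf7, the naive T cell factor TCF-1, was at -2.41. Probes of Pde3b and Themis lie near spot patches, and Igfbp4 and Themis were well above background on 2 of 3 Foxp3+ arrays.

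Of 15 immediate early and heat shock genes, 3 were higher and 12 did not pass, 11 being higher when adjusted over the list alone (median 0.84, camera adjusted p = 7.09e-11, and adjusted p = 0.258 with an estimated correlation). Atf3, a stress-response factor well above background on 2 of 3 Foxp3- arrays, was 4.35 higher, Dusp1 2.28 and Fosb 1.81. Of 22 activation and checkpoint genes, 4 were higher and 18 did not pass, with 9 higher and 2 lower when adjusted over the list alone (median 0.70, camera adjusted p = 0.000191, and adjusted p = 0.641 with an estimated correlation). They included Nr4a2, a factor induced by T cell receptor signals, at 3.43. Of 15 IL-2/STAT5 targets, 2 were higher and 13 did not pass, with 6 higher and 1 lower when adjusted over the list alone (median 0.62, camera adjusted p = 0.000191, and adjusted p = 0.295 with an estimated correlation), among them Cish, a feedback inhibitor of STAT5, at 2.65. Of 7 Th2 and Th17 genes, 1 was higher, Ccr6, a chemokine receptor whose probe lies near a patch, at 2.99, and 6 did not pass, with 5 higher and 1 lower when adjusted over the list alone (median 1.47, camera adjusted p = 0.00133, and adjusted p = 0.324 with an estimated correlation). The unfolded protein response list passed (13 genes, 0 past the threshold and 1 higher when adjusted over the list alone, median 0.50, camera adjusted p = 0.000309, and adjusted p = 0.627 with an estimated correlation). So did apoptosis genes (13 tested, 1 higher, 1 lower, Fasl, the death ligand, at -1.91, and 11 not passing, 3 higher and 1 lower when adjusted over the list alone, median 0.40, camera adjusted p = 0.00658, and adjusted p = 0.324 with an estimated correlation). The cytokine gene Il4 differed by -5.03 (adjusted p = 0.0591, well above background on 1 of 3 Foxp3+ arrays).

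None of 40 cell cycle genes passed alone, over all genes or adjusted over the list alone. Their list passed (median 0.64, camera adjusted p = 1.53e-06, and adjusted p = 0.733 with an estimated correlation) with medians of 0.26, 2.02 and -0.14 in the non-infected, day 3 and day 5 pairs. Of 7 dendritic cell markers none passed over all genes, 4 were lower when adjusted over the list alone, and the list was lower in Foxp3+ cells (median -1.94, camera adjusted p = 0.000540, and adjusted p = 0.627 with an estimated correlation). Itgax, an integrin of dendritic cells, differed by -3.58 (adjusted p = 0.115, well above background on 1 of 3 Foxp3+ arrays) and Cd74, the class II invariant chain, by -2.27 (adjusted p = 0.187). Plasma cell markers were higher as a list (6 genes, 0 past the threshold and 4 when adjusted over the list alone, median 1.34, camera adjusted p = 0.00528, and adjusted p = 0.324 with an estimated correlation). Erythroid markers passed with a day 3 pair of opposite sign (8 genes, median 0.78, with 0.63, -0.25 and 0.77 in the non-infected, day 3 and day 5 pairs, camera adjusted p = 0.0390, and adjusted p = 0.632 with an estimated correlation), of which 1, the transcription factor gene Gata1, passed at 2.58.

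In all, 175 genes were higher and 70 lower in Foxp3+ cells, 113 of these 245 being well above background on all 6 arrays, and 13 of 30 lists passed with camera at the preset correlation, against 0 with an estimated correlation. The latter test rests on the 2 residual degrees of freedom of the fit, so the loss of lists does not measure correlation alone. Gene counts were 365 higher and 377 lower in the authors' deposited table, 11 and 8 with the planned normexp correction, and 0 and 0 in limma with no filter on dim probes (1560 at an unadjusted p under 0.05). The planned normexp model could not describe the Foxp3+ non-infected array, and its refit gave 406 and 237. Only the day 5 pair lay within 1 slide. With slide as an added block, 0 genes passed in limma (925 at an unadjusted p under 0.05), and the median became that of the day 5 pair: 1.93 for Treg signature genes, 1.35 for suppressive mediators, -2.36 for conventional genes, 0.93 for immediate early genes, 0.14 for activation genes and -0.14 for cell cycle genes. Without the day 5 pair 11 genes were higher and 8 lower, without the non-infected pair 60 and 29, and without the day 3 pair 102 and 39.

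At day 3 of infection the Foxp3+ array was set against the non-infected Foxp3+ array on the same slide to ask how regulatory T cells respond early. Interferon-induced transcripts were among the highest: Ifit3, an antiviral effector, was 5.74 higher on the log2 scale, Oas2, an RNA sensor, 4.57 higher, and Ly6a, an interferon-induced surface protein, 4.96 higher. Mx1, an antiviral GTPase, was at least 23.2-fold higher, Rsad2, which encodes viperin, at least 19.0-fold higher and Ifi44 at least 29.7-fold higher. Tgm2, a transglutaminase, was 6.67 higher, the cytotoxic protease gene Gzmb 5.18, the surface protein gene Ly6c2 4.89, the pore-forming protein gene Mpeg1 4.63 and the histone gene H2ac4 5.25. Il10 was -0.44 from the reference and Il2ra 0.49.

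Of 33 measured type I interferon-stimulated genes, 31 were at least 2-fold higher and 0 lower, with a median of 2.74 (percentile 100 of random lists, whose central range was -0.05 to 0.47). The list of interferon-gamma-induced GTPases and antigen processing genes had 21 of 23 higher and a median of 1.54 (percentile 100), with Gbp6 at 2.18, Gbp2 at 2.10 and Irgm1 at 2.02. Cell cycle genes were higher in 24 of 25, with a median of 2.40 (percentile 100): Birc5, which encodes survivin, at 4.07, Rrm2, a ribonucleotide reductase subunit, at 3.91 and Uhrf1 at 3.81, while cyclin A2 (Ccna2) was at least 26.4-fold higher. Th1 genes had a median of 1.1 (percentile 100), with 5 of 10 higher, among them Cxcr6, a chemokine receptor, at 3.95 and Tbx21, the Th1 master regulator, at 2.66. Suppressive mediators had a median of 0.77 (percentile 99.9, 6 of 16 higher), with Lgals1, which encodes galectin-1, at 2.3 and Havcr2, which encodes TIM-3, at 1.77 (-0.17 with the planned normexp correction), and Treg signature genes had 0.49 (percentile 99.2, 13 of 37 higher). The median of the reference genes on this array, given under the other observations, was no smaller than that of the Treg signature genes.

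Conventional CD4 T cell genes were lower, with a median of -0.96 (percentile 0.01, 2 of 9 at least 2-fold lower and 0 higher), and naive and homing genes had a median of -0.76 (percentile 0, 2 of 15 lower and 1 higher). S1pr1, the receptor for exit from lymphoid organs, was at -1.46, and Bach2, a quiescence factor, at -0.96. Medians of both lists turned positive with the planned normexp background correction, at 0.83 and 0.97, where the median of all genes compared was 0.67, as did S1pr1 (0.51). That model could not describe the Foxp3+ non-infected array. Its refit on spots at or above their local background kept the sign of both lists, of S1pr1 and of Havcr2. Among markers of other cells in this fraction, Lyz2, the lysozyme of macrophages, was 3.03 higher, Cd74 (probe near a patch) 3.16 and H2-Ab1, a class II chain, 2.29. Dendritic cell markers had a median of 2.29 (3 measured, or 1.54 with floored members), B cell markers 0.68 (3 measured), and macrophage and monocyte markers 0.35 (6 measured).

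Among 11587 genes compared, 991 were at least 2-fold higher and 1083 lower at day 3 in Foxp3+ cells, so 47.8% of the changed genes were higher, against 67.3% in the authors' deposited table and 33.6% when scaled on probes above background on all arrays. All of the 10 lowest genes have probes in or near dark patches: Acap1 at -6.90, Mdn1 at -6.88, Vps37b at -6.21, Wasf2 at -6.14, Dhx32 at -3.73, Fundc1 at -3.73, Tspyl2 at -3.72, Nrn1 at -3.48, Gm11346 at -3.37 and Ptk2b at -3.25. Of the 10 highest, Psma5 at 6.71 and Zfp655 at 5.54 have probes in a patch that was dark on the non-infected array, and without genes in patches 871 were higher and 950 lower.

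At day 5 the Foxp3+ array, on slide 2, was set against the non-infected one on slide 1, so slide and infection cannot be told apart here. Gzmb was 5.48 higher, Cxcr6 4.86, the replication factor gene Mcm10 4.81, Birc5 4.71, the cohesion regulator gene Cdca5 4.66 and H2ac4 5.71. Il10 was 3.21 higher, from a level of 0.12 in non-infected cells and -0.32 at day 3 to 3.33 at day 5. Lag3, an inhibitory receptor, was 4.41 higher, Nkg7, a granule protein, 3.73 and Havcr2 3.50. The chemokine genes Ccl4 and Ccl3 were at least 129-fold and 24.2-fold higher. Blnk, a B cell signalling adaptor, was 4.74 higher.

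Cell cycle genes were higher in 24 of 25 (median 2.44, percentile 100), with Rrm2 at 4.18, Top2a, a topoisomerase, at 4.15 and Stmn1 at 4.07. Suppressive mediators had a median of 1.13 (percentile 100, 9 of 16 higher), Treg signature genes 0.68 (percentile 100, 12 of 37), Th1 genes 1.07 (percentile 100, 5 of 10, Tbx21 at 2.91) and activation genes 0.55 (percentile 99.9, 7 of 21). Type I interferon-stimulated genes had a median of 0.42 (percentile 99.7), with 7 of 33 higher: Oas2 was at 2.35 (-0.10 with the planned normexp correction), Cxcl10, a chemokine, at 1.63 and Isg15, a ubiquitin-like modifier, at 1.35. Interferon-gamma-induced genes had 0.47 (percentile 98.98, 2 of 23). Conventional genes had a median of -0.82 (percentile 0.03, 4 of 10 lower and 1 higher) and naive and homing genes -0.34 (percentile 0.3, 3 of 15 lower and 2 higher), with Bach2 at -1.28, Il7r, the IL-7 receptor, at -1.24 and S1pr1 at -1.07. Both of these medians turned positive with the planned normexp correction (0.56 and 1.60, with 0.60 for all genes compared), as did Bach2 (0.53), Il7r (0.59) and S1pr1 (0.99), and the naive and homing median was 0.10 in the authors' deposited table, where that of all genes compared was 0.42. The planned normexp model could not describe the Foxp3+ non-infected array. Its refit on spots at or above their local background kept the sign of both medians and of Oas2, Bach2, Il7r and S1pr1. Among markers of other cells, Lyz2 was 4.52 higher, Jchain, an antibody-joining chain of plasma cells, 4.15, Cd74 4.0 and Ms4a1, which encodes the B cell antigen CD20, at least 15.2-fold.

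Among 12086 genes compared, 783 were at least 2-fold higher and 1180 lower at day 5 in Foxp3+ cells, 39.9% higher, against 80.3% in the authors' deposited table. The 10 lowest were Itpripl1 at -4.73, Klf13 at -4.18 and Susd6 at -3.09, whose probes lie in dark patches, and Wnt10a at -3.45, Dscam at -2.92, Gm2974 at -2.73, Npb at -2.71, Slc35a1 at -2.67, Hal at -2.53 and Pex11g at -2.52. Psma5 (6.16) and Zfp655 (5.63) rest on the patch of the non-infected array.

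In Foxp3- cells at day 3, on the same slide as their reference, interferon-induced transcripts were again among the highest. Ly6a was 6.10 higher, Ifit3 5.81, Ifit3b 5.40 and Rsad2 5.38, and Cxcl9, a chemokine induced by interferon-gamma, was at least 88.1-fold and Oasl2 at least 239-fold higher. All 37 measured type I interferon-stimulated genes were at least 2-fold higher (median 3.09, percentile 100), with Cxcl10 at 4.92 and Ifi44 at 4.76. The interferon-gamma-induced list had 23 of 25 higher (median 2.41, percentile 100), with Ciita, the class II master regulator, at 4.42, Iigp1, an immunity-related GTPase, at 3.92 and Gbp2 at 3.43. Tgm2 was 6.51 higher. The same array had higher levels of transcripts typical of other cells, whose source stays open: Mpeg1 6.40, Blnk 5.51, the inflammatory cytokine gene Il1b 5.36, Pirb, a myeloid receptor, 5.21, Dnase1l3, a nuclease of dendritic cells and macrophages, 5.17, and Ms4a1 5.16.

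Markers of dendritic cells had a median of 4.22 (6 of 7 higher, percentile 100), B cells 3.09 (6 of 7, percentile 100), natural killer cells 3.19 (4 of 5, percentile 100), and macrophages and monocytes 1.21 (6 of 12, percentile 100). The natural killer members higher were Tyrobp, Fcer1g, Gzma and Eomes, and the last 2 are also in the cytotoxic list. The natural killer receptor gene Klrb1c was not higher, with levels of -3.19 in non-infected cells and -3.44 at day 3. With floored members the medians were 3.65 for dendritic cells, 1.76 for B cells and 1.57 for macrophages and monocytes. H2-Aa and H2-Ab1 were both 4.22 higher, Cd74 4.43, Cd79b, a B cell receptor chain, 3.09, Lyz2 4.03 and Tyrobp, a myeloid and natural killer adaptor, 4.87, while Siglech, of plasmacytoid dendritic cells, was at least 7.65-fold higher. Pax5, the B lineage factor, was at least 4.41-fold lower, and its probe lies in a bright patch of the non-infected array. T cell identity genes had a median of 0.13 (percentile 27.3), with 0 of 14 changed 2-fold, and Cd4 was at 0.02. Cell cycle genes had a median of 1.1 (15 of 29 higher, percentile 100), with Nusap1, a spindle protein, at 2.82 and Birc5 at 2.77. Activation genes had 0.55 (percentile 100, 6 of 20), follicular helper genes 0.70 (percentile 100, 1 of 10), Th1 genes 0.33 (percentile 96.5, 2 of 13), conventional genes 0.34 (percentile 94.1) and naive and homing genes 0.23 (percentile 65.7). Treg signature genes had 0.61 (percentile 100, 9 of 28) and suppressive mediators 0.74 (percentile 100, 6 of 12), with Cd274, which encodes PD-L1, at 2.87 and Gzmb at 2.58. Il10 was not well above background at day 3.

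Among 13538 genes compared, 886 were at least 2-fold higher and 235 lower at day 3 in Foxp3- cells, 79.0% higher, against 26.8% in the authors' deposited table. The 10 lowest were Eya2, a phosphatase and transcription co-activator, at -2.97, Gar1, a ribonucleoprotein of RNA pseudouridylation, at -2.86, Tmem186 at -2.25, Tmem273 at -1.99, Car12 at -1.94, Map7d2 at -1.83, Surf6 at -1.78, Tnpo2 at -1.76, Plekha7 at -1.71 and Mcph1 at -1.67. The level of Gar1 on this array, -2.21, lay apart from those on all other arrays, which were -0.08 to 1.45.

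At day 5 the Foxp3- array carried higher proliferation and helper transcripts. Gzmb was 6.83 higher, Mcm10 6.35, Sapcd2 6.27, Ccna2 6.03 and Ube2c, a mitotic ubiquitin enzyme, 6.0. Il10 was 6.14 higher, from -4.18 in non-infected cells to 1.96. Il21, the cytokine of follicular helper cells, was 5.64 higher, Cxcr5, the B cell follicle homing receptor, 4.55, Bcl6, the follicular helper master regulator, 4.08 and Pdcd1, which encodes PD-1, 3.67. Also high were Blnk at 6.28, Mpeg1 at 6.34, Sccpdh at 6.21 and Padi4, a deiminase of myeloid cells, at 6.10.

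Of 12 follicular helper genes, 11 were at least 2-fold higher (median 3.56, percentile 100), among them Angptl2 at 4.19 and Icos, a co-stimulatory receptor, at 3.65. Cell cycle genes had 28 of 31 higher (median 3.59, percentile 100), with Nusap1 at 5.94 and Birc5 at 5.75, and Cenpf, a centromere protein, was at least 64.8-fold higher. Activation genes had 16 of 22 higher (median 2.10, percentile 100), with Lag3 at 5.40, Ctla4 at 4.62 and Irf4, an activation-induced factor, at 3.05. Th1 genes had 10 of 15 higher and 2 lower (median 1.29, percentile 100): Ccl4 was at 5.05 and Ccl3 at 4.75, and Xcl1, a chemokine, was at least 3.96-fold lower. Treg signature genes had 17 of 31 higher (median 1.34, percentile 100) and suppressive mediators 7 of 14 (median 1.53, percentile 100, or 0.999 with floored members). Conventional genes had a median of -0.66 (percentile 0.01, 4 of 14 lower and 1 higher) and naive and homing genes -0.72 (percentile 0, 5 of 15 lower and 1 higher), with Dapl1 at -2.18, Il7r at -2.08, S1pr1 at -2.05 and Ccr7, the lymph node homing receptor, at -1.41. Without genes near patches on any of the 6 arrays the naive and homing median was 0.20 over the members left. Most patch spots lay on Foxp3+ arrays, which this comparison does not use. Bright patches on the arrays compared held 15 spots on Foxp3- non-infected (303 probes within reach) and 1 on Foxp3- day 5 (115 probes). Genes near these alone were not left out separately, so the cause of the change of sign was not tested. Type I interferon-stimulated genes had a median of 0.40 (percentile 94.6, 11 of 37 higher) and interferon-gamma-induced genes 0.58 (percentile 96.7, 8 of 25). B cell markers had a median of 2.86 (6 of 6 higher, or 2.20 with floored members), macrophage and monocyte markers 1.42 (8 of 12) and dendritic cell markers 1.44 (5 of 7), with Lyz2 at 4.56 and Ms4a1 at 4.82.

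Among 12593 genes compared, 1786 were at least 2-fold higher and 1120 lower at day 5 in Foxp3- cells, 61.5% higher, against 24.5% in the authors' deposited table and 43.0% when scaled on probes above background on all arrays. The 10 lowest were Tbc1d16 at -3.68, Rapgef4 at -3.53, Stk38, a Hippo pathway kinase, at -3.47, Cpne4 at -3.29, Gm2245 at -3.24, Eldr at -3.12, Ttc28 at -3.06, Tmem273 at -3.02, Dync1h1, the dynein heavy chain, at -3.01 and Eya2 at -2.92. The median of all genes compared was 0.06 for Foxp3+ day 3, -0.01 for Foxp3+ day 5, 0.04 for Foxp3- day 3 and 0.19 for Foxp3- day 5, whereas the authors' deposited values put it at 0.27, 0.42, -0.43 and -0.31.

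**Figure D3:**
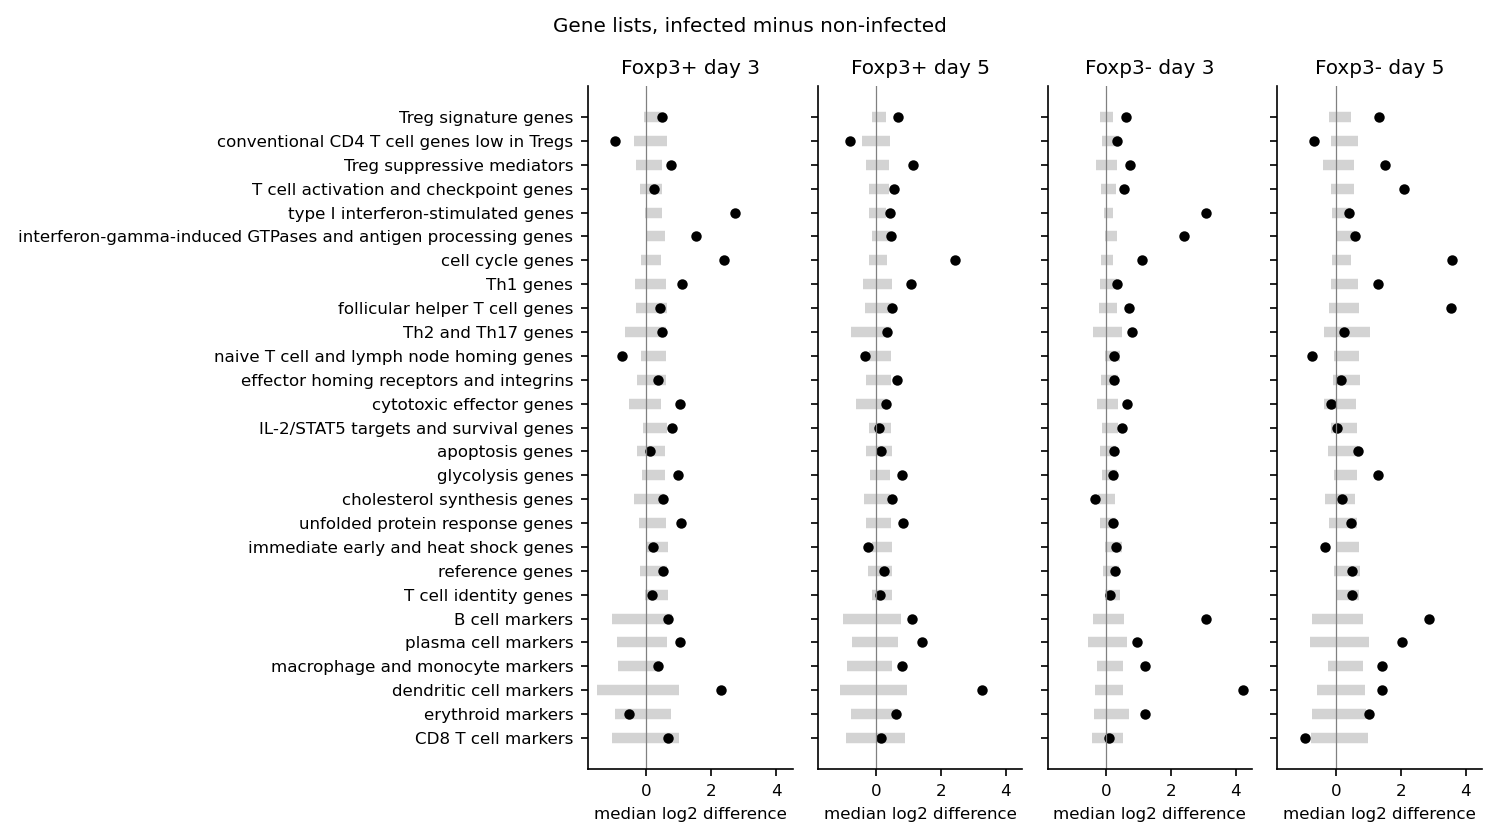
Median log2 difference between infected and non-infected arrays (x axis) of each gene list (y axis) in 4 comparisons of 1 array with 1 array. Black points are list medians and grey bars the central 95% of 10000 matched random lists; type I interferon-stimulated genes lie at 2.74 and 3.09 at day 3, follicular helper genes at 3.56 in Foxp3- cells at day 5. Naive and homing medians at day 3 and day 5 in Foxp3+ cells turned positive with the planned normexp correction, which moved the median of all genes to 0.67 and 0.60. That model could not describe the Foxp3+ non-infected array, and its refit kept both signs. The naive and homing median of Foxp3- day 5 turned positive without genes near patches on any array, most of which lay on Foxp3+ arrays.

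The day 5 array was also set against the day 3 array of the same cell type. Type I interferon-stimulated genes were lower by a median of -2.04 in Foxp3+ cells (34 of 37 at least 2-fold lower) and of -2.66 in Foxp3- cells (36 of 38), both at percentile 0, and interferon-gamma-induced genes by -1.19 (14 of 25) and -1.45 (16 of 25). Cell cycle genes differed by 0.40 in Foxp3+ cells (1 of 39 at least 2-fold higher) and by 2.71 in Foxp3- cells (31 of 34). Follicular helper genes differed by 0.22 and 2.57, and activation genes by 0.44 and 1.43. Beside these, dendritic cell markers differed by 0.91 and -1.90, B cell markers by 1.44 and 0.30, macrophage and monocyte markers by 0.93 and 0.06, erythroid markers by 1.47 and 0.74 and natural killer markers by 0.14 and -1.20. With floored members the B cell values were 0.93 and -0.02, and in Foxp3+ cells macrophage and monocyte markers had 0.59 and natural killer markers 0.36. Over all genes, 379 were at least 2-fold higher and 327 lower in Foxp3+ cells, across slides, and 1233 higher and 1209 lower in Foxp3- cells, within slide 2.

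Responses of both cell types were compared over genes measured on all 4 arrays of a day. At day 3, 244 of 11407 genes were at least 2-fold higher in both, against 45.1 for independent lists, and 61 lower in both, against 16.0, and the Pearson correlation of the log2 differences across genes was 0.417. At day 5, 531 of 11557 were higher in both, against 93.7, and 524 lower in both, against 86.3, with a correlation of 0.691. Genes are not independent replicates, and these comparisons share no array. Opposite 2-fold differences were found for 11 and 11 genes at day 3 (higher in Foxp3+ and lower in Foxp3-, or the reverse) and for 5 and 17 at day 5.

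**Figure D4:**
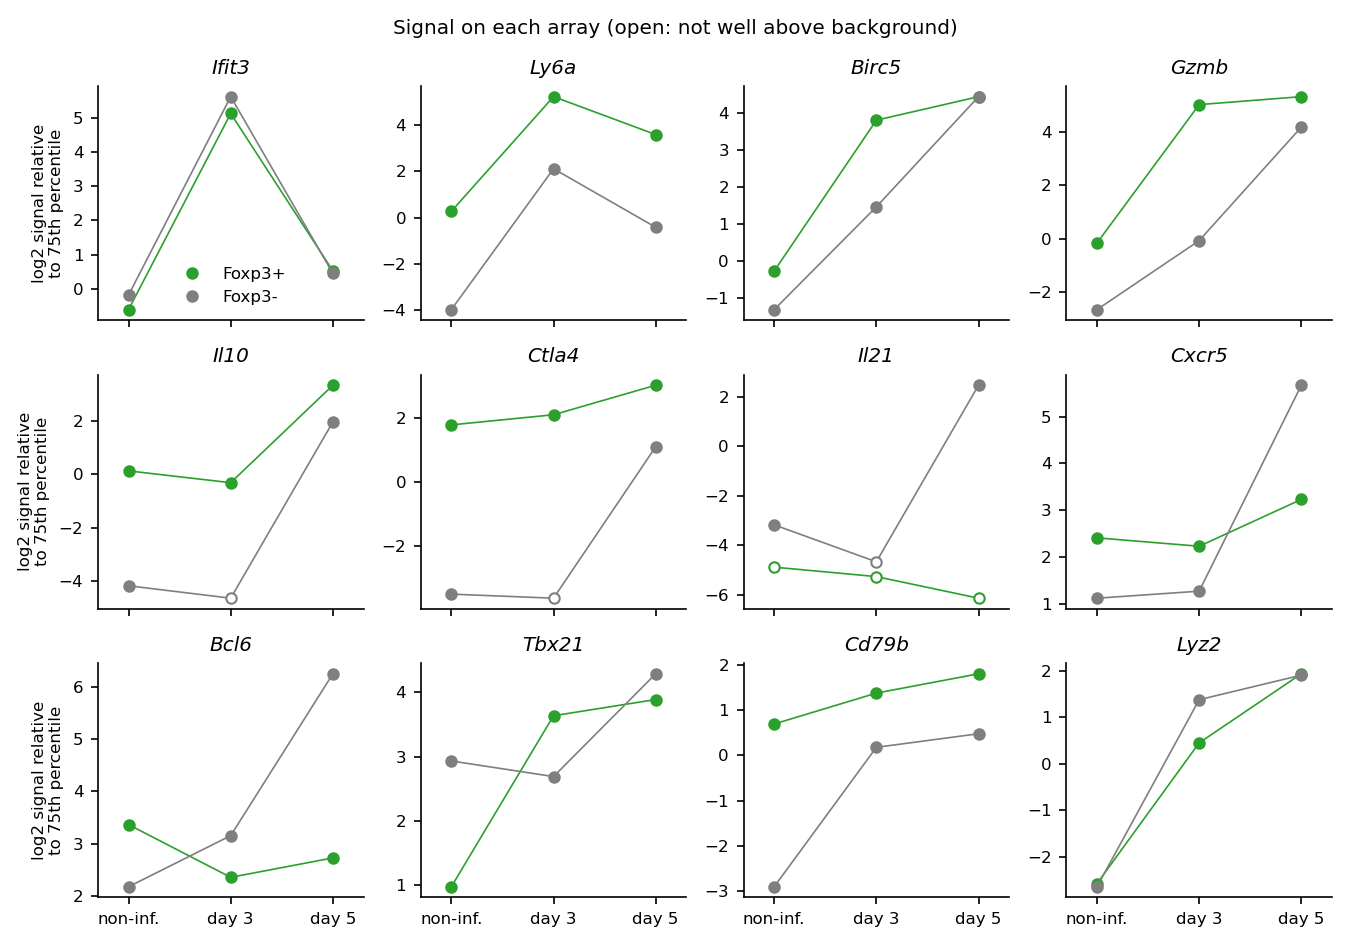
Log2 signal relative to each array's 75th percentile (y axis) on the non-infected, day 3 and day 5 arrays (x axis) for 12 genes in Foxp3+ (green) and Foxp3- cells (grey), 1 array per point, with open points not well above background. Ifit3 peaks at day 3 (5.13 and 5.62), and Il10 is highest at day 5 (3.33 and 1.96).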

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

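The genes and lists in this paragraph were picked because the single infected array of Foxp3+ cells moved one way and that of Foxp3- cells the other. With 1 array per group the difference was not tested for any of them. Values are the Foxp3- difference minus the Foxp3+ difference on the log2 scale. At day 3, the globin genes Hbb-bt (5.76, from -2.96 in Foxp3+ and 2.81 in Foxp3-) and Hba-a1 (3.52, from -2.32 and 1.20) were higher in Foxp3- and lower in Foxp3+ cells, and the erythroid list differed by 1.74 (-0.54 and 1.20), where -0.54 lies within the random range (percentile 12.5) and is -0.0373 with floored members. Cd83, a maturation marker, differed by 3.23 (-1.03 and 2.20), Gar1 by -4.20 (1.34 and -2.86), and the conventional CD4 T cell list by 1.30 (-0.96 and 0.34), where -0.96 turns to 0.83 with the planned normexp correction and 0.34 lies within the random range (percentile 94.1). The value of -0.96 kept its sign with the normexp model refitted on spots at or above their local background. The Gar1 difference rests on a level of -2.21 on the Foxp3- day 3 array alone, against -0.08 to 1.45 on the other arrays. The probe of Hba-a1 lies near a spot patch. At day 5, Gm2974 differed by 3.79 (-2.73 and 1.06), Socs2, a feedback inhibitor of cytokine signals, by -2.97 (1.16 and -1.82), and the CD8 T cell list by -1.09 (0.14 and -0.95), a difference that is lost with floored members (0.25 and 0.25).

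All tests in the rest of this part except the count over splits of the arrays were chosen after the results were seen, and the bounds of the marker share and of the carry-over test, and the genes of the activation and interferon tests, were revised after their values were known. The first pattern is the spots that were dark on 1 Foxp3+ array. Of 185 such spots on the 3 Foxp3+ arrays, 124 had neighbours of their kind, against at most 17 in 1000 random draws, a value a defect of the array surface needs. A change of transcript level in the cells is argued against by other probes of the same genes on that array, whose median difference was -0.0846 (67 genes, quartiles -0.40 and 0.14), while the dark probes had -3.76. Bright patches were not tested in this way.

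The second pattern is the transcripts of B cells and antigen-presenting cells in infected Foxp3- cells. If the interferon response of the sorted cells made them, those higher at day 3 would fall to day 5 as type I interferon-stimulated genes did (-2.66). The 5 B cell markers outside class II that were 2-fold higher had a median of 0.44 (quartiles 0.30 and 0.50), which argues against it for them. The 7 dendritic cell markers, class II genes among them, had -2.02 (quartiles -2.28 and -1.29), a value it needs. Among them Siglech (-0.007) and Xcr1 (-0.80) did not fall 2-fold. Picking markers for a high day 3 value favours a fall, and fewer carried cells at day 5 could give the same. The value therefore does not decide for dendritic cell markers. The 8 macrophage markers had -0.47 (quartiles -1.11 and 0.39), which decides nothing. Cells of other types in the sorted fraction stay open: 20 of 40 markers (50%) were at least 2-fold higher at day 3, by value or by bound. Of the 13538 genes compared by value, 6.5% were, so these markers were higher more often than genes at large. Among the markers, 7 were below background on both arrays, and Pax5 has its probe in a bright patch of the reference array. The share does not tell carried cells from a response of the sorted cells. With 1 array per group, cells carried along in the sort and infection cannot be told apart here.

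The third pattern is the Treg-associated genes higher in Foxp3- cells at day 5, such as Il10 and Ctla4. Foxp3+ cells carried into the sort would have to supply 25.2% (Ctla4) to 38.0% (Il10) of the Foxp3+ level. The 10 genes highest in Foxp3+ cells allow at most 13.9% (Dnah7a, median 2.48%) if the carried cells resemble the sorted ones. These genes were picked for large differences that include this same array, so low shares were partly built in. The test therefore does not decide whether carry-over was the whole source. Activation and helper differentiation of the Foxp3- cells stays open as a hypothesis: of 24 measured activation and follicular helper genes in neither Treg list, 17 (70.83%) were at least 2-fold higher, but both whole lists were known to be higher when this test was chosen. Other cells in the fraction are not excluded as a source.

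Before the data were examined, a count over the 10 splits of the 6 arrays into 3 against 3 was planned for the cell type comparison. The real split gave 245 genes and the highest other split 0 in limma, so 1 split gave as many. At an unadjusted p under 0.05 the real split gave 1863 and the highest other 2082. The splits with 2082 divided only the day 3 pair and kept both arrays of each other state together. They therefore hold the cell type difference at day 3 and are no grouping free of it. Splits that divided every pair but crossed the cell types gave 404, 342 and 150. With 10 splits the share is never under 0.05, so they are too few for this test.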

How the results depend on the processing

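Alternatives were planned before the data were examined, except scaling on probes above background on all arrays, leaving out genes in spot patches and the refitted normexp model, which were chosen after the data were seen. In the cell type comparison (175 higher, 70 lower) quantile normalization, the mean over probes, the stricter filter, the other scaling and leaving out patches kept both counts within 1.5 times (117 to 201 higher, 47 to 73 lower). The counts were 11 and 8 with normexp, 406 and 237 with its refit, 365 and 377 in the deposited table, 108 and 45 without the block for infection state, and 286 and 120 with a variance trend; the cause was not tested except for normexp. With no filter on dim probes they were 0 and 0 in limma (1560 genes at an unadjusted p under 0.05), over 27988 genes. With slide as a block they were 0 and 0 in limma (925 unadjusted), with 1 residual degree of freedom. Leave-one-out over pairs gave 11 to 102 higher and 8 to 39 lower, with 1 residual degree of freedom. The number of lists passing was 13 and went to 0 with an estimated correlation in camera, which then tests on the 2 residual degrees of freedom of the fit. IL-2/STAT5 targets had an estimated correlation of -0.0605, yet their unadjusted camera p went from 4.41e-05 to 0.0487. The loss therefore does not show that correlation between genes explains the lists.

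The planned normexp model could not describe the Foxp3+ non-infected array: its fitted background had a mean of -437 and an SD of 615, and the log2 values an SD of 0.66, against 1.56 after the refit. Under planned normexp, genes 2-fold higher were 4800 (Foxp3+ day 3), 4917 (Foxp3+ day 5), 586 (Foxp3- day 3) and 946 (Foxp3- day 5), and 2-fold lower 127 (Foxp3- day 3) and 650 (Foxp3- day 5). With the refit, 549 and 946 were higher in Foxp3- cells at day 3 and day 5, and 417, 326, 114 and 650 lower in Foxp3+ day 3, Foxp3+ day 5, Foxp3- day 3 and Foxp3- day 5. By the deposited values 1645, 2187, 470 and 801 were higher in that order, 537 lower in Foxp3+ day 5, 1285 in Foxp3- day 3 and 2468 in Foxp3- day 5; the cause was not tested. With signals floored and no filter, 14728 were lower in Foxp3+ day 5, and 13106 and 14451 higher in Foxp3- day 3 and day 5, since arrays differ in their floor. On genes above background on all 6 arrays, 511 were higher in Foxp3- day 3, with fewer genes compared.

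Of the 245 genes passing between cell types, 8 had the opposite sign under planned normexp. Planned normexp also moved the median of all genes compared to 0.67 at Foxp3+ day 3 and 0.60 at Foxp3+ day 5, so values near these mark a shift common to all genes. Signs turned for these named genes, 2-fold apart in the main values, under planned normexp, but for none of them with the refit. Foxp3+ day 3: Bbc3 0.55, Bcl6 0.88, Eomes -0.0495, Havcr2 -0.17, Jchain -0.28, S1pr1 0.51, Serpinb9 -0.54. Foxp3+ day 5: Bach2 0.53, Bcl2 0.96, Ccr6 0.58, Ctsw 0.33, Derl3 -0.63, Fcer1g -0.41, Il7r 0.59, Itga4 0.68, Oas2 -0.10, S1pr1 0.99. Susd6 at day 5 was 0.56 over its probes, another of which lies in a dark patch of the non-infected array. Among lists, planned normexp turned conventional (0.83) and naive genes (0.97) at Foxp3+ day 3, and conventional (0.56), immediate early (1.70), macrophage (-0.71) and naive genes (1.60) at Foxp3+ day 5. The deposited table turned immediate early (0.18) and naive genes (0.10) at Foxp3+ day 5, both below its median of 0.42 for all genes, and the normexp refit macrophage markers (-0.0861). Leaving out genes near patches on any array, most of them on Foxp3+ arrays, turned naive genes at Foxp3- day 5 (0.20). In the cell type comparison cell cycle genes turned with slide as a block (-0.14), follicular helper genes across leave-one-out (-0.50 without the day 3 pair, 0.75 without the day 5 pair) and macrophage markers under normexp (0.32). The follicular helper list passed without the day 5 pair (camera adjusted p = 0.0121), and macrophage markers passed under normexp (camera adjusted p = 0.00715). Beyond normexp and the left-out pairs the cause was not tested.

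Of the other values, 425 cell type list medians and 1354 values of named cell type genes kept direction and side of the threshold, 23 and 115 passed newly, and 24 and 190 no longer passed. In the infection comparisons 333 list medians and 998 gene values moved by less than the spot spread, and 438 and 1834 by more; a change of sign was counted only for genes at least 2-fold apart and for lists outside the central 95% of random lists. Signal over background limits dim genes, Foxp3 among them. The cell type test pairs arrays by infection state; replicate numbers gave no pairs, since each group holds only number 1.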

Other observations

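Glycolysis and unfolded protein response genes had medians above the central 95% of random lists in infected Foxp3+ cells, as had glycolysis genes in Foxp3- cells at day 5. Like all values of 1 array against 1 array these have no replicate check. Glycolysis genes had medians of 0.99 (8 of 17 at least 2-fold higher, percentile 99.99) in Foxp3+ cells at day 3, 0.79 (7 of 17) at day 5, and 0.22 and 1.30 (0 and 11 of 17) in Foxp3- cells. Hk2, which encodes hexokinase 2, was 3.61 higher in Foxp3- cells at day 5, Slc16a3, a lactate exporter, 4.34 and Tpi1 3.27. Unfolded protein response genes had medians of 1.08 (8 of 13 higher) and 0.84 (4 of 13) in Foxp3+ cells, against 0.22 and 0.46 in Foxp3- cells, both within the random range, and Sdf2l1, of the endoplasmic reticulum, was 2.24 higher in Foxp3+ cells at day 3. IL-2/STAT5 targets had 0.80 and 0.10 in Foxp3+ cells and 0.50 and 0.05 in Foxp3- cells at day 3 and day 5. Cytotoxic genes had 1.04 and 0.30 in Foxp3+ cells, and 0.65 and -0.14 in Foxp3- cells. With floored members the 2 day 5 values were 0.45 and 0.01.

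Cholesterol synthesis genes had medians of 0.52 and 0.48 in Foxp3+ cells, and -0.34 and 0.18 in Foxp3- cells at day 3 and day 5. Immediate early and heat shock genes had 0.20 and -0.25 in Foxp3+ cells, the latter 0.18 in the deposited table, and 0.31 and -0.34 in Foxp3- cells. Apoptosis genes had 0.13, 0.15, 0.26 and 0.69 over Foxp3+ day 3, Foxp3+ day 5, Foxp3- day 3 and Foxp3- day 5, effector homing receptors 0.37, 0.63, 0.25 and 0.16 (with floored members 0.75 and 0.53 at Foxp3+ day 3 and Foxp3- day 3), Th2 and Th17 genes 0.49, 0.33, 0.81 and 0.24, reference genes 0.53, 0.24, 0.26 and 0.49, and T cell identity genes 0.19, 0.13, 0.13 and 0.51. Follicular helper genes had 0.41 (0.25 with floored members) and activation genes 0.23 in Foxp3+ cells at day 3, and follicular helper genes 0.50 at day 5.

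Plasma cell markers had medians of 1.05, 1.41, 0.96 and 2.04 in the same order, erythroid markers -0.54 (-0.04 with floored members), 0.61, 1.20 and 1.04, and CD8 T cell markers 0.66, 0.14, 0.10 and -0.95, or 0.29, 0.25, 0.65 and 0.25 with floored members. B cell markers had 1.11 and dendritic cell markers 3.28 in Foxp3+ cells at day 5, with 3 genes measured each, or 1.54 and 0.23 with floored members. Macrophage markers had 0.81 there, and -0.71 with the planned normexp correction. Natural killer markers had 2.69 in Foxp3- cells at day 5 (1.56 with floored members), platelet markers 0.46 in Foxp3- cells at day 3 and stromal markers 0.50 in Foxp3- cells at day 5, each with fewer than 3 measured genes in Foxp3+ cells. The natural killer receptor gene Klrb1c was not well above background on the Foxp3- day 5 array. Neutrophil markers had fewer than 3 measured in each comparison with non-infected cells and 0.73 from day 3 to day 5 in Foxp3+ cells.

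Lists that did not pass between Foxp3+ and Foxp3- cells (camera) were type I interferon-stimulated genes (median -0.06, adjusted p = 0.564), interferon-gamma-induced genes (0.07, adjusted p = 0.194), Th1 genes (-0.47, adjusted p = 0.0549) and follicular helper genes (0.03, adjusted p = 0.719, turned from 0.94 in the non-infected to -1.38 in the day 5 pair). Naive and homing genes had 0.00 (adjusted p = 0.646), effector homing receptors 0.26 (adjusted p = 0.0836), cytotoxic genes -0.19 (adjusted p = 0.428), glycolysis genes 0.00 (adjusted p = 0.392), cholesterol synthesis genes 0.09 (adjusted p = 0.342), reference genes 0.18 (adjusted p = 0.454) and T cell identity genes -0.13 (adjusted p = 0.646). For markers of other cells the values were -0.11 for B cells (adjusted p = 0.507), -0.23 for macrophages (adjusted p = 0.646), 0.70 for neutrophils (adjusted p = 0.392), -0.78 for natural killer cells (adjusted p = 0.392), 0.69 for CD8 T cells (adjusted p = 0.646) and 0.07 for stromal cells (adjusted p = 0.721). Platelet markers, with 2 measured genes, were not tested.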
